A study of Danio rerio with 11 samples.

How the data were processed

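Gene expression was measured on Affymetrix zebrafish arrays in total RNA from whole zebrafish embryos. Each array carried RNA pooled from all 30 embryos of a cup, kept in 100 ml of medium. Exposed cups held 250 mg of oil emulsion spread on the cup bottom, and the emulsions came from the shoreline at 3 sites after the Deepwater Horizon blowout. Exposures lasted 48 h and ended at collection, at 48, 72 or 96 h post fertilization (hpf). The 11 arrays fell into 8 groups, and 6 of these groups had a single array. Controls numbered 1 array at 48 hpf, 3 at 72 hpf and 2 at 96 hpf. Groups and ages were taken from the sample titles.

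The deposited values are log2 probe set signals made by the authors with RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises the probes of a set), per the submitters' processing notes. The software that ran RMA and its version were not given in the sources used here. RMA quantile normalization gives all arrays nearly the same distribution of values, so a shift in total RNA per embryo would not be visible in these data. RMA also compresses small differences of dim probe sets. Array medians lay between 6.36 and 6.42 and lower quartiles between 4.72 and 4.82. No scanner files were used here, so no detection call per probe set was made.

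The table held 15617 probe sets. The 115 AFFX control probe sets were left out, which left 15502, and the 9803 with a log2 value of at least 6 in at least 1 of the 11 arrays were tested. Gene symbols came from the platform annotation and were updated by Entrez identifier through a RefSeq gene table of assembly GRCz12tu, which held 10711 of the identifiers and changed 1 symbol. Of the 15502 probe sets, 10795 had 1 symbol, 135 had several and 4572 had none; among those tested the numbers were 7570, 80 and 2153. Probe sets with several symbols or none were not named by gene. The tested probe sets covered 6466 gene symbols. Genome coordinates are not reported here, because the sources name no build for the array. Where a gene had several probe sets, the one with the highest mean over the 11 arrays stood for it, and no named gene had probe sets of opposite sign.

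Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the 9803 probe sets and a threshold of 0.05 on the adjusted p. The main comparison took the 3 exposed arrays at 72 hpf (1 per site) as 1 group against the 3 controls of that age. A second fit used all 11 arrays, with age as a factor. Single exposed arrays, differences between sites and the difference between exposure windows were contrasts in a fit with 1 mean per group, which left 3 residual degrees of freedom, all from the controls at 72 and 96 hpf. In that fit a lone array was assumed to vary like the controls. The control groups at 96 and 72 hpf were compared over the 6 control arrays. The 48 hpf pair had 1 array on each side and was described without a test, by the probe sets that differed by at least 1 on the log2 scale. Nothing in the labels says whether replicate control arrays came from separate cups or spawnings, so all p-values measure the spread between these arrays, which may be partly technical. The number of arrays limits the precision throughout.

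The position of each 72 hpf array between the control ages was the slope, through 0, of its difference from the 48 hpf control on the difference between the 96 and 48 hpf controls, over probe sets whose control values differed by at least 1 on the log2 scale. Positions were compared with a two-sided exact permutation test, for which the smallest p with 3 against 3 arrays is 0.1. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives. The 31 lists held 594 genes, of which 390 were on the array and 341 were tested, and 28 lists had at least 5 tested genes. For every list the calls of its members were also adjusted over the list alone. Correlations of responses that share the 72 hpf controls were set against 100 simulations of unchanged groups. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.

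Tests, lists, filters, alternatives and the rule for named genes were fixed before the data were examined. In the 72 hpf and age-adjusted comparisons the rule takes, in each direction, the 12 genes of largest difference among probe sets with 1 symbol that passed and showed no overlap between exposed arrays and their age-matched controls. Open places are filled by rank of unadjusted p from probe sets without overlap that differed by at least 1, and these are given as not passing. In single-array comparisons and between control ages it takes the 6 of largest difference in each direction past the threshold, and at 48 hpf the 6 of largest difference with at least 1 array of the pair at log2 8 or more. It also takes, at 72 hpf, 2 to 4 members of largest difference per list, and cyp1a in every comparison. Further list members named below were chosen after their values were seen.

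The fits were tested on simulated data with 9803 probe sets. In the 72 hpf comparison the simulation recovered 62% of the probe sets changed by 0.5 on the log2 scale, 94% of those changed by 1 and 100% of those changed by 2, with 5.82% of calls false. For Gulfport at 72 hpf 22% were recovered at 0.5 and 96% at 1, with 7.10% of calls false, and for Gulfport at 96 hpf 14% and 98%, with 6.59%. Simulated lone arrays were given the spread of the controls, so these rates cannot test the assumption that lone arrays vary like controls. For the age-adjusted fit the values were 88% and 100%, with 5.37%. For the difference between the Gulfport responses at 96 and 72 hpf only 4% were recovered at 0.5 and 54% at 1. For Gulfport minus Fort Morgan 8% were recovered at 0.5 and 82% at 1, with 5.84% of calls false. The comparison of control ages recovered 58% at 0.5 and 98% at 1, with 10.6% of calls false, above the nominal rate. In lists simulated with independent genes camera called only the shifted list of 28. That simulation cannot show how often camera passes lists whose genes vary together.

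Alternatives comprised no filter on dim probe sets (15502 tested), a mean log2 of at least 6 (8867 tested), repeated quantile normalization, median centring, a variance trend with robust moderation, a minimum log2 difference of 1, 1 probe set per gene, array weights, other sets of arrays, a replicate block for the control ages, and leaving out each array in turn. Under the rescalings the median difference over all probe sets stayed within 0.0508 of 0 in each comparison.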

Results

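Expression profiles were collected from zebrafish embryos exposed for 48 h to weathered oil emulsions from Gulfport, Fort Morgan and Perdido Key, and from unexposed embryos of the same ages. All 3 emulsions were tested at 24 to 72 hpf, with 1 array each and 3 control arrays. Gulfport emulsion was also tested at 0 to 48 hpf, with 1 control array, and at 48 to 96 hpf, with 2 control arrays. Age set the main difference among the 11 arrays: the first principal component held 63.3% of the variance and ordered the arrays by age. The second held 13.3%, and the Gulfport array at 72 hpf lay highest on it, at 19.5. Among the 3 control arrays at 72 hpf, 21, 36 and 41 tested probe sets differed by at least 1 on the log2 scale between any 2 arrays, and 75 did so between the controls at 96 hpf.

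The comparison of the 3 exposed with the 3 control arrays at 72 hpf asked which genes differ in embryos kept with emulsion. The gene cyp1a, a monooxygenase gene induced through the aryl hydrocarbon receptor (AHR), rose 59.7-fold, from a log2 value of 7.04 ± 0.17 (SD, n = 3) in controls to 12.94 ± 0.10 (SD, n = 3) in exposed embryos (log2 difference 5.90, SE 0.11, limma adjusted p = 1.55e-07). Its relative cyp1c1 rose 14.8-fold (log2 difference 3.89, SE 0.26, limma adjusted p = 0.000667). A further cytochrome P450 gene, cyp2k18, rose 13.7-fold (log2 difference 3.78, SE 0.21, limma adjusted p = 0.000429), from a dim control value of 3.89 ± 0.12 (SD, n = 3) to 7.67 ± 0.47 (SD, n = 3).

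**Figure D1:**
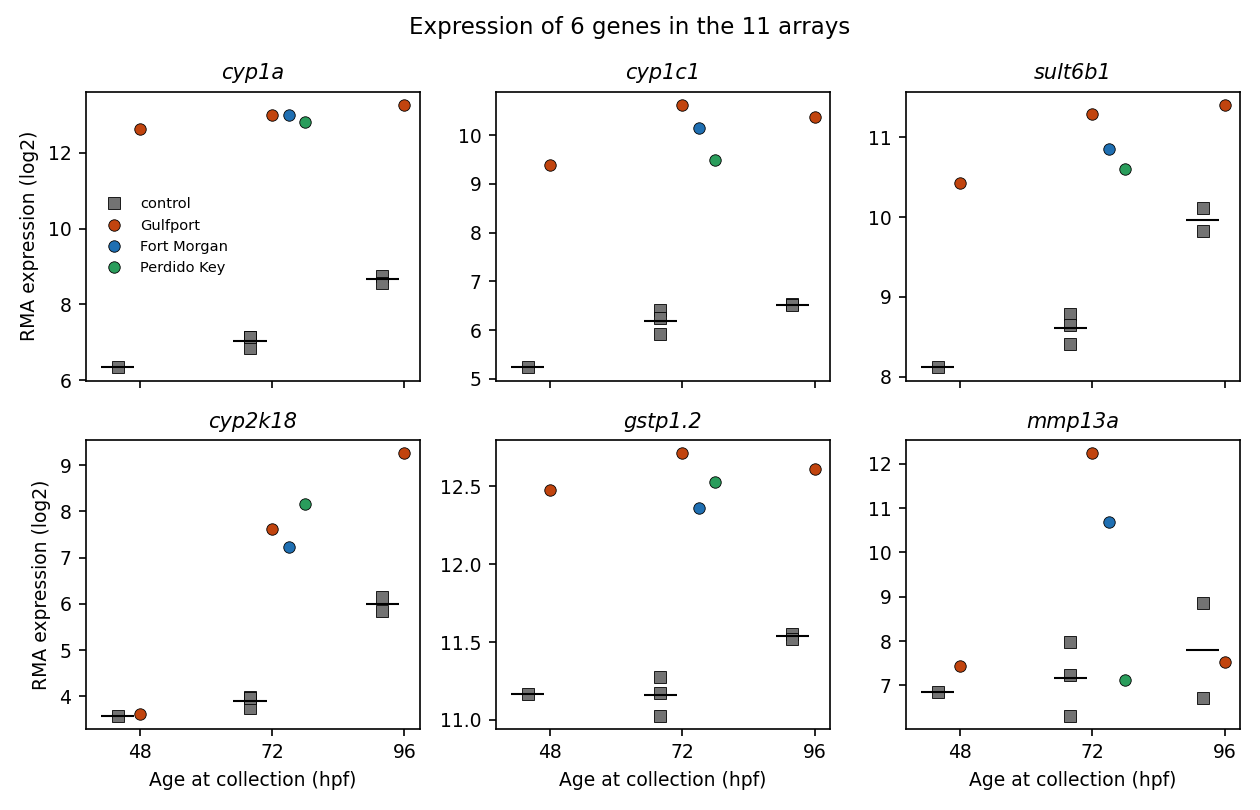
RMA log2 values (y axis) of cyp1a, cyp1c1, sult6b1, cyp2k18, gstp1.2 and mmp13a in each of the 11 arrays, by age in hours post fertilization (x axis); squares are control arrays with a black line at their mean, and circles are exposed arrays coloured by site. For cyp1a the exposed arrays at 72 hpf averaged 12.94 and the controls 7.04, while cyp2k18 differed by 0.04 between the pair of arrays at 48 hpf.

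The other named rises were smaller. The sulfotransferase gene sult6b1 rose by 2.30 on the log2 scale (SE 0.18, limma adjusted p = 0.00157), the cytochrome b5 gene cyb5a by 1.77 (SE 0.14, adjusted p = 0.00166) and the UDP-glucose dehydrogenase gene ugdh, whose product supplies the substrate of glucuronidation, by 1.65 (SE 0.10, adjusted p = 0.000503). Glutathione S-transferase genes gstp1.2, gstt1b and gsto2 rose 2.59-fold, 2.48-fold and 2.30-fold, and the glutathione reductase gene gsr 2.33-fold. The carbonyl reductase gene cbr1l rose by 1.14 and the cytochrome P450 gene cyp2y3 by 1.12. Adjusted p-values of these 6 genes lay between 0.000503 and 0.0202. The falls of epd (ependymin) and ccl34b.1 (a chemokine) measured -1.33 and -1.24, and those of lgals3bp.1, pde6a (a subunit of the rod phosphodiesterase), f7i and muc5.1 (a mucin) measured -0.92, -0.88, -0.87 and -0.70. The cartilage transcription factor gene sox9b fell by 0.56 on the log2 scale (SE 0.09, limma adjusted p = 0.0401). The next genes in rank did not pass: the rod transducin gene gnat1 differed by -1.46 (limma adjusted p = 0.0549), the elastase gene cela1.6 by -1.40 (0.0999) and krt15 by -1.14 (0.172). The trypsin gene prss1 differed by -1.17 (0.305) and the rod transducin gene gngt1 by -1.42 (0.312). These calls depended on the arrays and settings. The gene gnat1 passed without Gulfport (0.0151) or Perdido Key (0.0285), with no filter (0.0453), with median centring (0.0480) and with array weights (0.0252). Without Perdido Key cela1.6 (0.0441) and krt15 (0.0285) passed. All 5 passed as the mean of the site contrasts with the spread of controls only (0.000775 to 0.00659). With array class (arrays grouped by the lower quartile of their values) as a block, an alternative chosen after the data were seen, krt15 passed (0.0392) and epd (0.0505) and sox9b (0.0515) did not.

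In all, 56 of 9803 probe sets passed, 47 higher and 9 lower, and these covered 39 named genes. At this age 858 had an unadjusted p under 0.05. Exposed and control arrays did not overlap in 1323 probe sets (13.5%, against 10% by chance), and all 56 calls were among these. The count depended on single arrays: it was 23, 24 and 32 without control replicate 1, 2 or 3, each with 1 lower, and 28 without Fort Morgan, with 1 lower. Without Perdido Key it was 83 (58 higher, 25 lower) and without Gulfport 45 (38 higher, 7 lower). Of the named falls only lgals3bp.1 passed without each of the 6 arrays. Among the named rises gsto2 missed the threshold without any 1 of the controls (adjusted p = 0.0800 to 0.0871), and cbr1l without control replicate 3, Gulfport or Fort Morgan (0.0539 to 0.0865).

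Of the lists fixed beforehand, the AHR battery and the Nrf2 list had the most calls over all genes tested at 72 hpf. Of the 8 measured genes of the AHR battery, 6 rose over all genes tested and 7 adjusted over the list alone, with a median log2 difference of 1.11. These included ahr2, the receptor gene, at 0.86, and tiparp, a repressor of the receptor, at 0.81; nqo1 and tgm2b did not pass, at 0.40 and 0.11. The list passed camera (limma adjusted p = 4.03e-21; adjusted p = 0.0498 with an estimated correlation). Of 17 genes of Nrf2 and oxidative stress, 5 rose and 12 did so adjusted over the list alone, with a median of 0.71 (camera adjusted p = 2.04e-16; adjusted p = 0.0817 with an estimated correlation). The members that rose were gsr, gstp1.2, the Nrf2 gene nfe2l2a (0.90) and the glutamate-cysteine ligase genes gclc (0.78) and gclm (0.71). At 1.44, 1.28 and 1.18, the probe sets standing for prdx1, sqstm1 and txnb did not pass, while 2 other probe sets of prdx1 did, at 1.70 and 1.52. The genes catalase (cat) and sod2 lay at -0.18 and 0.00. The gene gstp1.2 belongs to both lists. By fry, 2 lists passed, the same AHR and Nrf2 lists.

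Camera at its preset correlation passed 10 further lists, none of which held with an estimated correlation. Their medians were small except for phototransduction and exocrine pancreas. Phototransduction genes had a median of -0.62 (16 genes, 1 fell, 2 adjusted over the list alone; camera adjusted p = 7.79e-08), with gnat1 at -1.46, pde6a at -0.88 and gnat2 at -0.85. Digestive enzyme genes of the exocrine pancreas had a median of -0.68 (15 genes, 0 fell, 11 adjusted over the list alone; adjusted p = 4.25e-10), with prss1 at -1.17 and ctrb.1 at -1.16. Both lists rose with age between 72 and 96 hpf in controls, by medians of 0.76 and 3.68. With an estimated correlation the adjusted p = 0.542 for each of the pair. Cell cycle genes had a median of -0.16 (19 genes, none above 0; adjusted p = 0.000866), neuron genes of -0.28 (11 genes, none above 0; 0.00159), complement and acute phase genes of -0.16 (10 genes, 2 fell adjusted over the list alone; 0.00887) and retinoid and visual cycle genes of -0.29 (8 genes; 0.0369). Medians above 0 were found for p53 and DNA damage (0.26, 9 genes; 0.00632), hypoxia response (0.15, 10 genes; 0.00247), cholesterol synthesis (0.20, 9 genes; 0.00730) and myeloid and inflammation (0.32, 13 genes; 0.0499). The members of largest difference were mcm2 (-0.27) and tyms (-0.26) of the cell cycle, tubb5 and gad1b (both -0.37) of neurons, cp (-0.61) and plg (-0.48) of complement, and stra6 (-0.50) and cyp26a1 (-0.41) of the retinoid list. In the other 4 they were gadd45aa (1.07) and ddb2 (0.34), igfbp1a (0.91) and igfbp1b (0.55), msmo1 (0.64) and cyp51 (0.47), and mmp13a (2.84) and mmp9 (1.86). No member of these 4 lists, nor of the cell cycle, neuron, complement and retinoid lists, passed over all genes. With an estimated correlation the adjusted p = 0.542 for 7 of these 8 lists and 0.604 for the myeloid list. The myeloid list did not pass without control replicate 1 (0.0809), control replicate 2 (0.281) or Gulfport (0.791). The retinoid list did not pass without control replicate 1 (0.108), control replicate 3 (0.0776), Gulfport (0.121) or Fort Morgan (0.0565). Cholesterol synthesis did not pass without control replicate 2 (0.0797), complement without control replicate 3 (0.102) or Perdido Key (0.237), and cell cycle without Perdido Key (0.0828).

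The other lists did not pass camera at 72 hpf. Heart muscle (8 genes) had a median of -0.02 (adjusted p = 0.730) and skeletal muscle (17 genes) one of -0.00 (0.820), whose sign turned under either rescaling and opposed the direction camera gave. Liver secretory genes (16 genes) had a median of -0.09 (0.503) with 1 rise, cyp2y3, and cartilage, bone and matrix genes (16) one of -0.07 (0.482) with 1 fall, sox9b. Xenobiotic phase I and II enzymes (14) had a median of -0.02 and a mean of 0.36 (0.126), with 1 rise, cyp2k18, and 3 adjusted over the list alone. Intestine and lipid absorption genes (9) had a median of 0.12 (0.0757) with 1 rise, the fatty acid binding protein gene fabp1b.1 at 0.81. Epidermis and keratin genes (19) had a median of -0.15 (0.0664), with 0 falls over all genes and 3 adjusted over the list alone: krt15, krt17 and krt94. Without Perdido Key this list passed (0.0213), as it did without control replicate 3 (0.00204). Leaving out 1 array also passed heat shock (without Fort Morgan 0.0333, without Perdido Key 0.0390) and cartilage (without Perdido Key 0.0378). Without control replicate 3 or Gulfport, intestine (0.00333 and 0.0182) and the circadian clock (0.00241 and 0.00765) passed, as did xenobiotic enzymes without Gulfport (0.0370). All these passes, with those of the epidermis list, are at the preset correlation. With every 72 hpf array and an estimated correlation the camera adjusted p of these lists lay between 0.542 and 0.830. Medians were 0.10 for heat shock and unfolded protein (15; 0.0802), 0.08 for the circadian clock (14; 0.0658), 0.04 for erythroid genes (10; 0.317) and 0.07 for endocrine pancreas and pituitary (8; 0.845). They were -0.01 for lipid and fatty acid metabolism (7; 0.797, camera direction up), -0.09 for ionocytes (6; 0.637) and -0.02 for glia and myelin (9; 0.761). Medians of 0.10 for glucocorticoid and metal response with a mean of -0.05 (9; 0.735), and of 0.02 for metabolic and ribosomal reference genes (15; 0.439), completed the set. Lens crystallin, cardiac calcium and potassium handling, and endothelium had 3, 4 and 4 measured genes and were not tested by camera; their medians were -0.29, -0.02 and -0.00, with 1 fall adjusted over the list alone, the lens gene cryaa. Of the members of largest difference in these lists, cyp2k18, cyp2y3, sox9b and fabp1b.1 passed. The others, which did not pass, included cyp3a65 (1.31), ces3 (-0.53), matn1 (-0.32), vil1 (0.48), krt15 (-1.14) and krt17 (-0.92). For heart muscle they were bmp4 (0.43) and myl7 (-0.21), for skeletal muscle pvalb3 (-0.40) and myog (0.18), and for heat shock atf3 (0.91) and dnajb1b (0.37). The clock had cry5 (0.49) and tefa (0.38), erythroid genes nt5c2l1 (0.54) and hbbe2 (-0.42), and the endocrine list prl (0.47) and neurod1 (-0.27). Lipid metabolism had fads2 (0.46) and lpin1a (-0.42), ionocytes ca2 (-0.20) and clcn2c (-0.18), and glia mbpa (-0.31) and slc1a2b (-0.28). The glucocorticoid list had klf9 (-0.89) and sgk1 (0.68), and the reference genes ubb (0.21) and actb2 (0.11). In the 3 lists not tested by camera these were cryba4 (-0.33) and crybb1 (-0.29), fkbp1b (0.24) and atp2a2a (-0.04), and tie1 (0.22) and flt4 (-0.08).

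**Figure D2:**
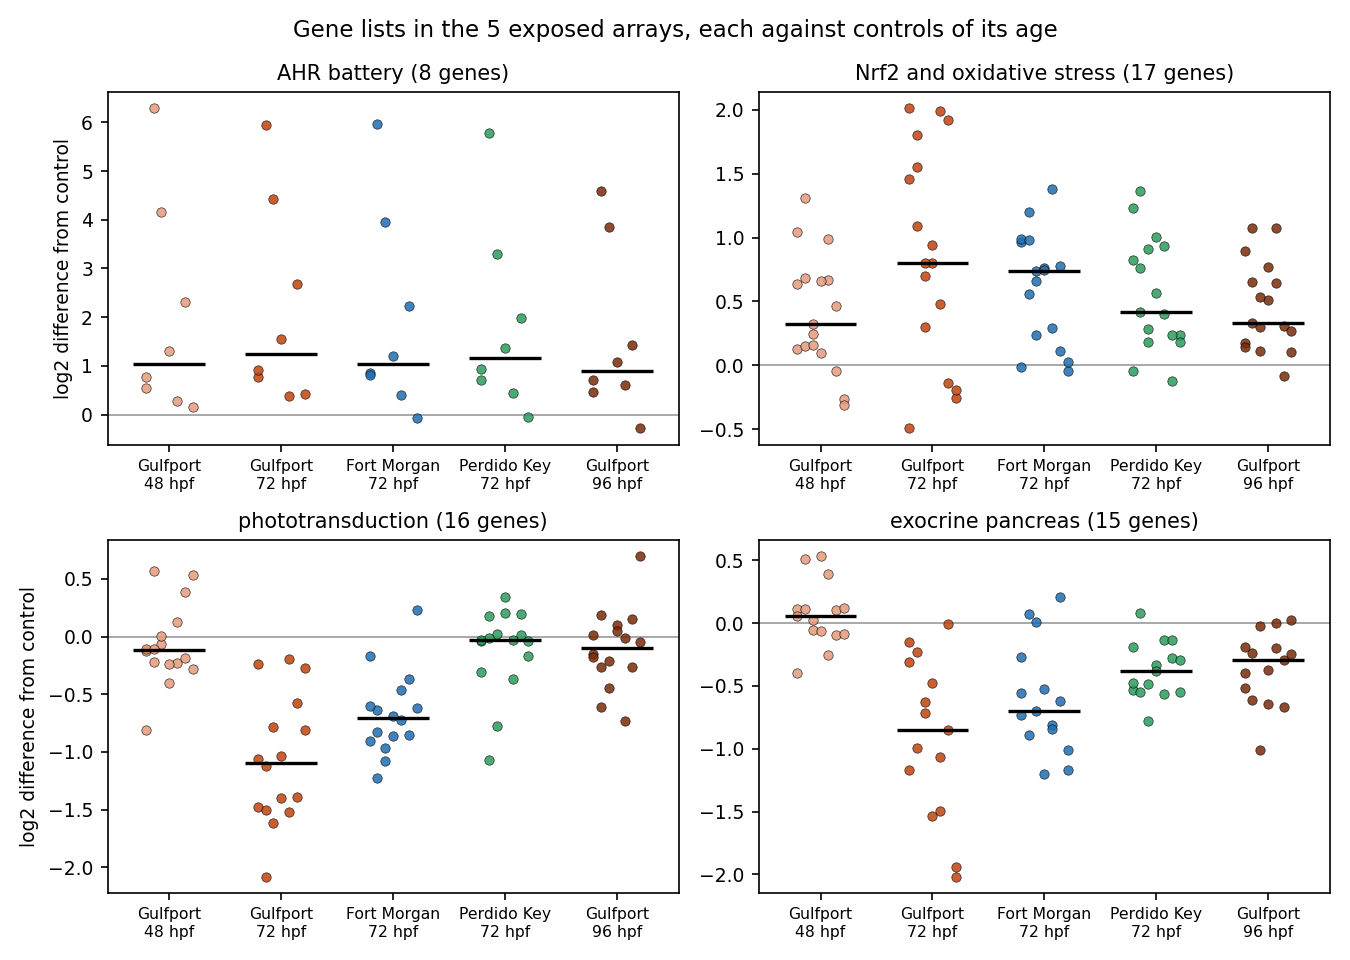
Log2 difference from the age-matched control mean (y axis) for each measured member of the AHR battery (8 genes), Nrf2 (17), phototransduction (16) and exocrine pancreas (15) lists in the 5 exposed arrays (x axis); points are genes and the black line is the median. Phototransduction medians at 72 hpf were -1.09 for Gulfport, -0.71 for Fort Morgan and -0.03 for Perdido Key.

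Across all ages, with age as a factor, the largest rises were those of cyp1a (50.1-fold, log2 difference 5.65, SE 0.20, limma adjusted p = 8.41e-08) and cyp1c1 (15.3-fold, 3.93, SE 0.17, adjusted p = 2.57e-07), then cyp2k18 (7.70-fold, 2.95, SE 0.44, adjusted p = 0.00543). The cyp2k18 value averages unlike windows, because at 48 hpf its control and Gulfport values were both dim (3.58 and 3.62) and differed by 0.04. Next came sult6b1 at 2.08, cyb5a at 1.58, gstp1.2 at 1.29, the peroxiredoxin gene prdx1 at 1.26, ugdh at 1.26 and cyp3a65 at 1.21. Genes of unassigned function among the largest rises were wu:fj05g07 (1.54), si:dkey-247k7.2 (1.32) and si:ch211-207n23.2 (1.26). The falls of ccl34b.1, krt15, epd and lgals3bp.1 measured -1.07, -0.99, -0.96 and -0.83. They were followed by zgc:112964 and f7i at -0.81 and -0.76, elovl4b (fatty acid elongase) at -0.76, muc5.1 at -0.71, the complement factor D gene cfd at -0.69, lgals2b (a galectin) at -0.61, the ceruloplasmin gene cp at -0.53 and sox9b at -0.52.

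The age-adjusted fit called 128 probe sets (105 higher, 23 lower, 96 named genes), and 1115 had an unadjusted p under 0.05. Of the 128, 126 lay on one side of the age-matched controls at all 3 ages, as did 511 of all 9803 tested. At 48 hpf a lone array always lies on 1 side of its lone control, and the calls came from these same arrays. The 126 are therefore no separate support for the calls. In this fit 7 of 8 AHR battery genes rose (7 adjusted over the list alone; camera adjusted p = 2.88e-24, and adjusted p = 0.00738 with an estimated correlation). Of the Nrf2 list 8 of 17 rose (12 adjusted over the list alone; camera adjusted p = 3.20e-19, and adjusted p = 0.0158 with an estimated correlation). Xenobiotic enzymes had 3 of 14 rise (5 adjusted over the list alone; camera adjusted p = 0.0288; adjusted p = 0.392 with an estimated correlation). Exocrine pancreas had 0 fall and 10 adjusted over the list alone (camera adjusted p = 1.25e-07; adjusted p = 0.381 with an estimated correlation), and phototransduction 0 and 2 (camera adjusted p = 5.40e-05; adjusted p = 0.392 with an estimated correlation). Camera passed 12 of 28 lists, and only the AHR and Nrf2 lists held with an estimated correlation. Of the epidermis list krt15 and krt94 fell. Lower calls numbered 12 without Fort Morgan (97 in all) and 14 without 72 hpf control replicate 2 (106 in all). Without the Gulfport array at 96 hpf the count was 81, with 14 lower, and krt15 (adjusted p = 0.0654) and zgc:112964 (0.103) did not pass. The latter also missed without Fort Morgan (0.0521). The calls of cyp3a65, elovl4b and lgals2b were lost without any of 7, 8 and 9 of the 11 arrays (adjusted p up to 0.155, 0.131 and 0.119). The call of cp was lost without 72 hpf control replicate 3, Fort Morgan or either 48 hpf array (0.0545 to 0.0723), and that of epd without Fort Morgan or any of the 3 controls at 72 hpf (0.0718 to 0.0849). With only Gulfport and controls cyp2k18 did not pass (2.60, adjusted p = 0.0650), nor did cyp3a65 (0.151), epd (0.126), f7i (0.0530), lgals2b (0.0650) or cp (0.0856). With a variance trend and robust moderation cyp3a65 (0.0761) and epd (0.0513) did not pass.

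The Gulfport array at 72 hpf had the most calls of the 3 sites. Besides cyp1a (61.9-fold, log2 difference 5.95, SE 0.16, limma adjusted p = 4.14e-06), cyp1c1 (21.4-fold, 4.42, adjusted p = 5.18e-05) and cyp2k18 (13.3-fold, 3.73, adjusted p = 5.18e-05), mmp13a, mmp9 and timp2b rose. The collagenase gene mmp13a rose 33.5-fold (log2 difference 5.07, SE 0.79, adjusted p = 0.0180), the gelatinase gene mmp9 16.0-fold (4.00, SE 0.75, adjusted p = 0.0345) and timp2b, which encodes an inhibitor of such enzymes, 8.53-fold (3.09, SE 0.47, adjusted p = 0.0168). Control arrays varied for these 3 genes, with SDs of 0.83, 1.09 and 0.45 (n = 3). The largest falls of named genes were gngt1 at -2.39, gnat1 at -2.08, the chymotrypsin gene ctrb.1 at -2.02, cela1.6 at -1.99, prss1 at -1.94 and epd at -1.84, with limma adjusted p-values from 0.00145 to 0.0168.

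By list, 10 of 17 Nrf2 genes rose in the Gulfport array (13 adjusted over the list alone) and 6 of 8 AHR genes (8 adjusted over the list alone). Of 16 phototransduction genes 9 fell (12 adjusted over the list alone, median -1.09), among them the cone opsin genes opn1sw1 (-1.48) and opn1mw1 (-1.39), and of 15 pancreatic genes 5 fell (10 adjusted over the list alone, median -0.85). Of 13 myeloid and inflammation genes 3 rose (4 adjusted over the list alone): mmp13a, mmp9 and the cytokine signalling suppressor socs3b (1.72). The neutrophil gene mpx and the lysozyme gene lyz lay at 0.04 and -0.25. These 5 lists passed camera. With an estimated correlation the adjusted p = 0.292 for AHR, 0.412 for Nrf2, phototransduction and pancreas, and 0.573 for myeloid. The Gulfport array had a lower quartile of 4.80, within the control range of 4.72 to 4.81, and lay at 0.494 on the control age axis, against 0.533, 0.555 and 0.608 in the controls. Camera passed 9 further lists. Their medians were 0.33 for p53 (1 rise, mdm2 at 0.84; 3 adjusted over the list alone), 0.33 for heat shock (1 rise, dnajb1b at 1.07; 3), 0.22 for hypoxia (0; 1) and 0.36 for cholesterol synthesis (0; 1). They were -0.48 for the retinoid list (1 fall, rlbp1a at -0.65; 5 adjusted over the list alone), -0.45 for neurons (0; 5), -0.33 for cartilage (0; 1) and -0.23 for the cell cycle (0; 0). The liver secretory list had a median of -0.44, with 1 rise, cyp2y3 at 1.23, and 2 falls, fabp10a at -0.97 and tfa at -0.77 (1 and 7 adjusted over the list alone). Camera adjusted p-values of these 9 lay between 0.000196 and 0.0124, and with an estimated correlation the adjusted p lay between 0.412 and 0.579. By fry the AHR and Nrf2 lists passed. The epidermis list did not pass camera (0.392), but 3 of its genes rose, cldnb by 1.14, krt18a.1 by 1.07 and epcam by 0.68, and krt15 fell, at -1.68 (3 and 4 adjusted over the list alone). Single rises were nt5c2l1 (0.76) of the erythroid, fabp1b.1 (0.81) of the intestine and cyp2k18 of the xenobiotic list, none of which passed camera (1, 1 and 3 adjusted over the list alone). In total 266 probe sets passed, 171 higher and 95 lower, over 190 named genes, and 1664 had an unadjusted p under 0.05. Without control replicate 1 at 72 hpf the count was 320 (170 higher, 150 lower), and without replicate 2 or 3 it was 106 (36 lower) and 100 (32 lower). In the fits without replicate 2 or 3 mmp13a (adjusted p = 0.0506 and 0.0643), mmp9 (0.0521 and 0.103) and timp2b (0.0562 and 0.0601) did not pass, nor did ctrb.1 without replicate 2 (0.0594). With a variance trend and robust moderation mmp13a, mmp9 and timp2b did not pass either (0.182, 0.237 and 0.0652), nor did mmp9 with array class as a block (0.0543).

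Fort Morgan and Perdido Key each gave 22 calls, with cyp1a, cyp1c1 and cyp2k18 the largest. In the Fort Morgan array cyp1a rose 62.2-fold (log2 difference 5.96, limma adjusted p = 4.11e-06), cyp1c1 15.6-fold and cyp2k18 10.1-fold. There sult6b1, cyb5a and ugdh rose by 2.24, 1.84 and 1.53, while gnat1 and epd fell by 1.23 and 1.19 on the log2 scale (both adjusted p = 0.0303). In the Perdido Key array cyp1a rose 55.2-fold (5.79, limma adjusted p = 5.17e-06), cyp2k18 19.2-fold, cyp1c1 9.80-fold, sult6b1 by 1.98, ugdh by 1.59 and cyb5a by 1.53. AHR battery rises numbered 4 of 8 in each (6 and 7 adjusted over the list alone), and Nrf2 rises 2 and 4 of 17 (11 and 9 adjusted over the list alone). Phototransduction genes had a median of -0.71 in Fort Morgan embryos, with 1 fall and 10 adjusted over the list alone (camera adjusted p = 6.88e-13; adjusted p = 0.538 with an estimated correlation). Their median in Perdido Key embryos was -0.03, without a call. Fort Morgan and Gulfport had a high lower quartile (4.79 and 4.80) and Perdido Key a low one (4.73). Against the controls of their own array class the phototransduction medians were -0.62 for Fort Morgan (2 controls) and -0.18 for Perdido Key (1 control). Exocrine pancreas medians against the same controls were -0.81 and -0.28. Camera passed 7 of 28 lists for Fort Morgan and 11 for Perdido Key, and 0 of these held with an estimated correlation. The gene mmp13a differed by 3.52 in Fort Morgan embryos (limma adjusted p = 0.234) and by -0.05 in Perdido Key embryos. Calls numbered 22 for Fort Morgan (20 higher, 2 lower; 648 at an unadjusted p under 0.05) and 22 for Perdido Key (22 higher, 0 lower; 466). For Fort Morgan the count was 12 without 72 hpf control replicate 2 and 14 without either 96 hpf control, and 21 with 7 lower without 72 hpf control replicate 1. Its gene gnat1 missed the threshold without control replicate 2 or 3 at 72 hpf or either 96 hpf control (adjusted p = 0.0794 to 0.119), and epd without any of these 5 controls (0.0501 to 0.117). With array class as a block neither passed (0.0645 and 0.0705). For Perdido Key cyb5a missed it without 72 hpf control replicate 1 (0.0841) or 2 (0.0514).

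Whether the 3 sites differed was tested directly. No probe set passed between Gulfport and Fort Morgan (0 by limma, 558 at an unadjusted p under 0.05, smallest adjusted p = 0.201) or between Fort Morgan and Perdido Key (0 by limma, 470, smallest adjusted p = 0.942). With 1 array per site, the simulated Gulfport minus Fort Morgan contrast recovered only 8% of changes of 0.5 and 82% of changes of 1. Between these sites 84 probe sets differed by at least 1 on the log2 scale, 71 higher and 13 lower in Gulfport. The lack of calls therefore does not show that the sites were alike. Between Gulfport and Perdido Key 6 probe sets passed, 5 higher and 1 lower (1026 at an unadjusted p under 0.05). The liver fatty acid binding protein gene fabp10a was lower in Gulfport, at -1.78 (SE 0.20, limma adjusted p = 0.0448), and zgc:111983 was higher, at 1.37 (SE 0.16, adjusted p = 0.0448). The response of cyp1a did not differ detectably, at -0.01, 0.16 and 0.17 for Gulfport minus Fort Morgan, Gulfport minus Perdido Key and Fort Morgan minus Perdido Key (limma adjusted p = 1, 0.835 and 0.966). The 6 calls became 0 without 72 hpf control replicate 2 or 3 and 16 without 72 hpf control replicate 1 (9 lower) or either 96 hpf control (1 lower), and Gulfport minus Fort Morgan gave 3 without either 96 hpf control. With array class as a block, in which Gulfport and Perdido Key differ, the count was 0, with fabp10a at -1.94 (adjusted p = 0.168) and zgc:111983 at 1.34 (0.233), and that fit had 1 residual degree of freedom fewer. The difference of cyp1a then turned to -0.084 for Gulfport minus Perdido Key and -0.078 for Fort Morgan minus Perdido Key. Camera passed 11, 14 and 8 of 28 lists for the 3 differences in the same order, and 0 held with an estimated correlation. Among them was phototransduction for Gulfport minus Perdido Key (median -1.07, 0 fell, 11 adjusted over the list alone, adjusted p = 6.38e-10), with adjusted p = 0.531 with an estimated correlation.

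Responses at the 3 sites were compared across genes, which are not independent replicates. Pearson's r was 0.680 between Gulfport and Fort Morgan, 0.433 between Gulfport and Perdido Key and 0.441 between Fort Morgan and Perdido Key, against 0.252 in simulations of unchanged groups with the same controls. The covariances were 0.0653, 0.0364 and 0.0259, against 0.00767 simulated, which leaves differences of 0.0576, 0.0287 and 0.0182. Of 20 probe sets higher in Fort Morgan 19 were also higher in Gulfport (0.349 for independent lists), of 22 higher in Perdido Key 21 were (0.384), and 16 were shared by Fort Morgan and Perdido Key (0.0449). The 3 shared controls could not be split into sets of at least 2 arrays each, so part of the excess may come from them. The site contrasts also used the same variance per probe set, so their calls are not independent lists and part of the overlap may come from the fit. With no control in common, the Gulfport response at 96 hpf correlated with those at 72 hpf at 0.211 for Gulfport, 0.325 for Fort Morgan and 0.460 for Perdido Key. The Gulfport response at 48 hpf, also without a shared control, gave 0.356, 0.422 and 0.286 in the same order. By lower quartile the 96 hpf Gulfport array was of the class of Perdido Key, and the 48 hpf one of that of Gulfport and Fort Morgan. Array class therefore cannot be separated from this order.

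After exposure from 48 to 96 hpf to Gulfport emulsion 9 probe sets were higher. The gene cyp1a rose 24.2-fold (log2 difference 4.60, limma adjusted p = 5.06e-05), cyp1c1 14.5-fold (3.85, adjusted p = 0.000238) and cyp2k18 9.56-fold (3.26, adjusted p = 0.000238), followed by cyb5a (1.59, adjusted p = 0.0451), the heme synthesis gene alas1 (1.31, 0.0245) and gstt1b (1.24, 0.0190). AHR battery genes rose in 2 of 8 cases (7 adjusted over the list alone) and Nrf2 genes in 0 of 17 (7 adjusted over the list alone). Cholesterol synthesis genes had a median of -0.47 (0 of 9 fell; camera adjusted p = 2.22e-06; adjusted p = 0.536 with an estimated correlation), and heart muscle genes one of -0.27 (0 of 8 fell, 2 adjusted over the list alone; camera adjusted p = 0.00110; adjusted p = 0.498 with an estimated correlation), with cmlc1 at -0.58 and myl7 at -0.50. Camera passed 12 of 28 lists, and 0 held with an estimated correlation. None of the 9 was lower (454 at an unadjusted p under 0.05), and all 9 were also higher in the Gulfport array at 72 hpf (0.157 for independent lists). Both contrasts used the same variance per probe set, so the lists are not independent and part of the overlap may come from the fit. The count of calls was 17 with array class as a block (15 higher, 2 lower), 5 without 72 hpf control replicate 2 or 3 and 14 without 96 hpf control replicate 1 (6 higher, 8 lower). Both cyb5a and alas1 missed the threshold without any of the 5 replicated controls (adjusted p up to 0.214 and 0.154), and gstt1b without 72 hpf control replicate 2 or 3 or either 96 hpf control (up to 0.138). With only the 96 hpf arrays these 3 did not pass (0.168 to 0.171), and cyb5a did not with a mean log2 of at least 6 (0.0507) or repeated quantile normalization (0.0523).

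At 48 hpf, after exposure from fertilization, the Gulfport array differed from its single control by 6.30 for cyp1a (78.5-fold), 4.15 for cyp1c1 (17.8-fold) and 2.30 for sult6b1 (4.94-fold), with no replicate of either array. The cathepsin gene ctss2.1 differed by 1.78, cbr1l by 1.47 and si:dkey-247k7.2 by 1.39. In contrast to the later windows, cyp2k18 differed by 0.04. The lower genes included the immediate early genes fosab (-2.46) and nr4a1 (-1.55), then ankrd9 (-1.43) and gadd45ba (-1.32), with cebpd and jdp2b next, each 2.30-fold lower. A difference of at least 1 was found in 54 probe sets, 26 higher and 28 lower. Set against the spread of the control replicates at 72 and 96 hpf, only 6 probe sets passed, 5 higher and 1 lower. These were cyp1a, 2 probe sets of cyp1c1, sult6b1, ankrd9 (limma adjusted p = 0.0455) and 1 without a gene name. The others named did not pass, with adjusted p = 0.201 for ctss2.1, 0.239 for cbr1l, 0.385 for nr4a1, 0.491 for gadd45ba and 1 for si:dkey-247k7.2, fosab, cebpd and jdp2b. Of the 47 probe sets higher at 72 hpf, 45 were also higher at 48 hpf (16 by at least 1) and 47 at 96 hpf (21 by at least 1); of the 9 lower, 8 and 9 were lower.

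The difference between the Gulfport responses at 96 and 72 hpf was tested as an interaction. It gave 0 calls by limma (953 at an unadjusted p under 0.05, smallest adjusted p = 0.0745), and cyp1a differed by -1.36 (SE 0.24, limma adjusted p = 0.178). Without 96 hpf control replicate 1 the count was 50 (3 higher, 47 lower), and without replicate 2 it was 1. Camera passed 13 of 28 lists, and 0 held with an estimated correlation. The cyp1a value in the Gulfport array was 12.99 at 72 hpf and 13.26 at 96 hpf. Its controls lay at 7.14, 6.84 and 7.13 at 72 hpf and at 8.76 and 8.57 at 96 hpf. The smaller cyp1a response at 96 hpf thus went with higher control values, not with a lower exposed value.

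Unexposed embryos at 96 hpf were compared with those at 72 hpf. The elastase genes ela2l and ela2 rose 71.2-fold and 40.0-fold, the chitinase gene chia.2 55.9-fold, the chymotrypsin gene ctrb.2 48.3-fold, the ileal fatty acid binding protein gene fabp6 33.9-fold and the gene cell 25.6-fold. There cyp1a rose 3.09-fold (log2 difference 1.63, limma adjusted p = 0.000189). The largest falls were zgc:112964 (-2.11), zgc:86738 (-1.63), the purine synthesis gene paics (-1.60), the pigment cell gene pmelb (-1.56), dao.1 (-1.46) and si:dkey-239j18.3 (-1.45). Of 15 exocrine pancreas genes 14 rose (median 3.68; 14 adjusted over the list alone), of 9 intestinal genes 6 (median 1.94; 7) and of 14 xenobiotic enzymes 9 (10). Of 9 cholesterol synthesis genes 6 rose (6) and of 16 phototransduction genes 10, with 1 fall, crx (12 and 1). In contrast 4 of 10 erythroid genes fell (8 adjusted over the list alone, median -0.57). All 6 lists passed camera, as did 10 of the other lists. With an estimated correlation the adjusted p = 0.235 for pancreas, intestine, xenobiotic enzymes and erythroid genes, 0.372 for cholesterol and 0.437 for phototransduction. In total 941 probe sets passed (617 higher, 324 lower; 2571 at an unadjusted p under 0.05). The count was 613 and 551 without 72 hpf control replicate 1 or 2, and 500 and 382 without 96 hpf control replicate 1 or 2. The gene pmelb missed the threshold without 96 hpf replicate 1 (adjusted p = 0.0805), dao.1 without 96 hpf replicate 2 (0.125), and si:dkey-239j18.3 without 72 hpf replicate 1 or either 96 hpf control (0.0623 to 0.116) or with a variance trend and robust moderation (0.0609).

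On the control age axis (0 at 48 hpf, 1 at 96 hpf, 1181 probe sets) the controls at 72 hpf lay at 0.533, 0.555 and 0.608 and the exposed arrays at 0.494 for Gulfport, 0.523 for Fort Morgan and 0.598 for Perdido Key. The exposed mean of 0.538 ± 0.054 (SD, n = 3) did not differ detectably from the control mean of 0.566 ± 0.039 (SD, n = 3), with a difference of -0.027 (two-sided exact permutation p = 0.5, smallest possible 0.1). The axis kept genes changed by exposure. Induced genes that rise with age in controls, such as cyp1a, move exposed arrays to older positions. Genes that rise with age and were lower in exposed arrays, such as pancreatic enzyme genes, move them to earlier ones. The positions therefore do not measure age alone. The size and sign of the difference between exposed and control means depended on the arrays and the setting. It was 0.000442 with the median of the ratio in place of the slope. Over probe sets whose control ages differed by at least 2 or 0.5 on the log2 scale it was -0.0512 and -0.0175. Without control replicate 1 or 3 at 72 hpf it was -0.0435 and -0.00592, and without Gulfport or Perdido Key -0.00538 and -0.0572.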

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

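The contrast of the Gulfport responses at 48 and 72 hpf, the tests of developmental delay and of array class, the block for array class and the simulation of the shared 48 hpf control were chosen after the results were seen.

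Between Gulfport and Perdido Key at 72 hpf 6 probe sets differed by the test of the difference itself, all with a limma adjusted p = 0.0448. The fall was that of fabp10a, at -1.78 (SE 0.20). Higher in Gulfport were both probe sets of zgc:111983, at 1.48 (SE 0.16) and 1.37 (SE 0.16), pfkfb3, a gene of glycolysis control, at 1.49 (SE 0.16), and 2 probe sets without a gene name, at 2.11 (SE 0.24) and 1.45 (SE 0.17). All except fabp10a and zgc:111983 fall outside the naming rule and were chosen after their values were seen. With 1 array per site, a site and a cup cannot be separated, and without control replicate 2 or 3 at 72 hpf the count was 0. Perdido Key also had the low lower quartile of control replicate 2 (4.73 and 4.72) and Gulfport the high one of the other controls, and with that array class as a block the count was 0.

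The Gulfport response of cyp2k18 was lower at 48 than at 72 hpf, by -3.69 on the log2 scale (SE 0.26, limma adjusted p = 0.00592), and this was the only call among 579 probe sets at an unadjusted p under 0.05. Its values at 48 hpf were 3.58 in the control and 3.62 in the Gulfport array, while at 96 hpf the controls had 5.85 and 6.15 and the Gulfport array 9.26. The 48 hpf pair and the Gulfport array at 72 hpf are single arrays, so the SE assumes that they vary like the controls at 72 and 96 hpf. The values at 48 hpf are dim, so the size of the difference is uncertain. One hypothesis was that genes called higher at 72 hpf respond less at 48 hpf where their control level rises with age. Across 29 genes, which are not independent, Spearman's rho was -0.065 (permutation p = 0.738), with a bootstrap interval of -0.471 to 0.363. Both quantities subtract the same 48 hpf control array, whose noise alone moved rho to a mean of 0.0378 in simulations without a relation, so the bound of -0.1 set in advance against the hypothesis was too easily met; the interval also spans it, and the hypothesis stays open. The 48 hpf value of cyp2k18 itself was known when this test was planned.

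Photoreceptor and pancreatic enzyme genes were low in the Gulfport array at 72 hpf, with medians of -1.09 (95% bootstrap interval -1.48 to -0.78) and -0.854 (-1.17 to -0.48). These intervals resample the genes of a list in 1 array, so they measure spread between genes, not between arrays or cups. Since both lists rise with age in controls, a developmental delay of that cup may account for the low values. Over 757 other age-dependent genes the array lay at 0.512 on the age axis, against 0.556 ± 0.040 (SD, n = 3) in controls, a delay of 2.11 h that, at each gene's faster control rate of the spans 48 to 72 and 72 to 96 hpf, would give medians of -0.279 and -0.331, and at its upper bound of 6.56 h -0.866 and -1.03, inside both intervals. The other genes were not cleared of exposure-induced genes that rise with age in controls, such as cyp1a (by 2.33 from 48 to 96 hpf) and cyp2k18 (2.42). Their induction moves an exposed array toward an older position, so the delay may be larger than estimated. At the 48 to 72 hpf rates the upper bound would give -0.866 and -0.344, the latter smaller than its interval allows, but these rates assume a steady rise while the pancreatic list rose by 1.26 and then 3.68, so its rate near 72 hpf is unknown and delay and a direct effect cannot be told apart for either list. Array class was set here by a cut at the middle of the range of lower quartiles, with no scan date or batch label behind it. Gulfport (4.80) and control replicates 1 and 3 (4.79 and 4.81) were of the high class and control replicate 2 (4.72) of the low one. The Gulfport array at 48 hpf, at 4.77, lay close to the cut. Against the 2 controls of its class the medians of the 72 hpf Gulfport array were -1.02 (-1.32 to -0.717 over genes) and -0.883 (-1.58 to -0.529 over genes). The low values thus did not come only from a comparison across classes. Yet the photoreceptor median went with class across sites (-0.71 in Fort Morgan, of the high class, and -0.03 in Perdido Key, of the low class), and controls of the high class lay lower than those of the low class by medians of -0.224 at 72 and -0.134 at 96 hpf, so class may add to that difference between sites. For the pancreatic list the medians against controls of the same class were -0.81 in Fort Morgan (2 controls) and -0.28 in Perdido Key (1 control). Low pancreatic values were thus not limited to the Gulfport cup. An effect of the emulsion or of the Gulfport cup stays open, since Gulfport had 1 array at this age.

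The count of 56 probe sets at 72 hpf was set against the other ways to part the 6 arrays into 3 and 3. The 10 splits are too few for a share under 0.05; the real split gave 56 and the highest other, control replicate 1, Gulfport and Fort Morgan against the rest, gave 5. For the age-adjusted comparison 1 of 100 splits within age, the real one, gave as many as 128, and the highest other gave 19. This share is under 0.05, but it argues against chance only if the arrays of an age are independent. The labels do not say whether replicate controls came from separate cups or spawnings, so this stays uncertain.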

How the results depend on the processing

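The block for array class was added after the data were seen; it gave 62 calls at 72 hpf and 209 for Gulfport at 72 hpf, 17 for Gulfport at 96 hpf and 0 for Gulfport minus Perdido Key, and cyp1a reversed to -0.084 in Gulfport minus Perdido Key and -0.078 in Fort Morgan minus Perdido Key. Over all alternatives 133 values for whole comparisons stayed within 1.5 times the main count or kept their direction and side of the threshold, 46 counts moved further and 1 value reversed. Of the 133, 12 were age positions, for which the smallest exact p is 0.1, so only their direction could change. Counts of 0 that stayed at 0 gave 12 for Fort Morgan minus Perdido Key, 10 for Gulfport minus Fort Morgan and 9 for the difference between Gulfport responses. The total of 133 thus overstates stability. For named genes 1398 values kept direction and call, 156 lost the call, 13 gained it and 2 reversed. The cause was not tested unless given.

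With a minimum log2 difference of 1, which by construction can only remove calls, the counts were 30 at 72 hpf, 32 adjusted for age, 154 for Gulfport at 72 hpf and 265 between control ages. At 72 hpf the mean of the site contrasts with the spread of controls only gave 129, and 1 probe set per gene, with fewer tested, gave 36. Only Gulfport and controls gave 75 in the age-adjusted fit. A variance trend with robust moderation gave 41 for Fort Morgan, 36 for Perdido Key, 26 for Gulfport at 96 hpf and 2 for the difference between its responses. Only the array itself and its 3 controls gave 14 for Fort Morgan. For Gulfport at 96 hpf no filter gave 18, a mean log2 of at least 6 gave 5 and only the 96 hpf arrays gave 5. At 48 hpf the spread of the control replicates gave 6 calls (5 higher, 1 lower). The difference in age position was 0.000442 with the median of the ratio (exact p = 1), the reversed value. Lists passing numbered 1 with an estimated correlation and 2 with fry.

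Leaving out 1 array gave 23 to 83 calls at 72 hpf, 81 to 124 adjusted for age, 100 to 320 for Gulfport, 12 to 21 for Fort Morgan and 17 to 20 for Perdido Key at 72 hpf, 5 to 14 for Gulfport at 96 hpf, 0 to 3 for Gulfport minus Fort Morgan, 0 to 16 for Gulfport minus Perdido Key, 0 for Fort Morgan minus Perdido Key, 0 to 50 for the difference between Gulfport responses, 382 to 788 between control ages, -0.0572 to -0.00538 for position and 10 to 13 lists. Numbers of control replicates at 72 and 96 hpf did not pair the arrays (correlations of deviations -0.0499 and -0.0647 for numbers 1 and 2), and the replicate block gave 784 calls. Signal over background was not measured per array here, and dim probe sets such as that of cyp2k18 in controls have uncertain folds.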

Other observations

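The list of immediate early genes and its test were chosen after the spread of these genes was seen; the test is the only one in this part.

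Immediate early genes, which cells switch on rapidly after stimulation, varied widely between arrays. Of 19 listed genes 13 were measured. Their list mean was 6.69 and 8.80 in the controls at 96 hpf, 6.93 and 6.20 in the control and Gulfport arrays at 48 hpf, and 7.40, 6.28 and 7.04 in the Gulfport, Fort Morgan and Perdido Key arrays at 72 hpf. In the 3 controls at 72 hpf it was 6.90, 6.965 and 7.73, and in the Gulfport array at 96 hpf 6.97. The median difference between the controls at 96 hpf was 2.27, against 0.123 over all genes, and the median control SD was 0.397 against 0.117.

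One hypothesis was that exposure lowers these genes. The mean difference between exposed and age-matched control arrays was -0.60 (exact permutation p = 0.342 over 120 assignments within age), 2 exposed arrays lay below all their controls and 0 above, so an effect of exposure and a difference in handling between cups cannot be told apart. The spread may bear on the lower values of fosab and nr4a1 in the 48 hpf pair.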
